A study of Danio rerio with 8 samples.

How the data were processed

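The data were 8 Affymetrix zebrafish gene arrays of whole-retina RNA from albino zebrafish (Danio rerio), 4 from unlesioned controls and 4 from fish with a light lesion, a loss of photoreceptors produced by intense light. Per the labels' protocols, fish were first adapted to darkness, after which some were kept for 72 h in constant bright light and the others went back to ordinary lighting. RNA was extracted with the RNaqueous kit and labelled with biotin by in vitro transcription, per the labels. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether the replicates were separate fish or pools, so the p-values measure only the spread between these samples, which may be technical.

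The authors deposited 1 log2 value per probe set and array, made with RMA per the submitters' processing notes. RMA normally corrects background, applies quantile normalization and summarises the probes of a probe set. Its version, the software and the steps run are not given in the sources used here. The base of the logarithm is not stated and was read from the range of the values, which ran from 5.47 to 14.89. The arrays had medians of 7.62, 7.65, 7.69 and 7.65 in control replicates 1 to 4 and of 7.66, 7.64, 7.62 and 7.65 in light lesion replicates 1 to 4. The values were not centred per gene, and the direction of each comparison follows from the labels.

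The file held 15617 probe sets, of which 115 control probe sets (names starting with AFFX) were left out, leaving 15502. The array annotation gave 1 gene symbol for 10795 of these, several for 135 and none for 4572, and probe sets with several symbols or none were counted but not named. Of the symbols, 10711 were found through their gene identifiers in the RefSeq gene table and 1 was updated. A gene was read from its probe set of highest mean over the 8 arrays, which gave 8793 genes, 1539 of them with more than 1 probe set. No genomic coordinates are given, because the files name no genome build.

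Light lesion and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate, no filter on dim probe sets), with Benjamini-Hochberg adjustment over the 15502 probe sets and a threshold of 0.05 on the adjusted p. A log2 fold change is the light lesion mean minus the control mean. Of the 30 gene lists fixed before the data were examined, each was tested against the other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The difference between the rod and cone lists was tested on each array's mean over a list with an exact two-sided permutation test over all 70 assignments of the 8 arrays, whose smallest possible p is 0.0286. The lists covered photoreceptors, retinal neurons and glia, regeneration, the cell cycle, inflammation, stress, metabolism, ribosomal proteins and cells from outside the neural retina.

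The genes named were fixed by a rule before the data were examined: mdka and mdkb; the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, leaving out provisional symbols; for each list up to 3 genes past the threshold in the direction of its median and 1 in the other, or otherwise the 2 of smallest p; and pcna, ascl1a, stat3, gfap, rho, opn1mw1 and sox2 where measured. A probe set of rho alone was not analysed here. The following members of small counts lie outside this rule and were chosen after their values were seen: rx2, samd11, gngt2a, rbp3, fgf24, glula, rpe65a, rgrb, gpx1a, tp53inp1, sod2, fth1a, ccl19a.1, cxcl14, ccn2a, btg1, klf11a, gap43, cxcr4b, thy1, slc16a3b and gapdh.

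Alternatives fixed before the data were examined were the replicate number as a block, a second quantile normalization, median centring, leaving out dim probe sets, a trended and robust variance prior, array weights, leaving out each array, averaging the probe sets of a gene, a threshold of 0.01, and for lists the other tests and the removal of genes held by several lists. A background covariate and the other probe sets of each named gene were added after the data were seen. The second quantile normalization and median centring moved the median log2 fold change of all probe sets from -0.04 to -0.03 in both cases.

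The steps were tested on simulated arrays for the light lesion against control comparison, with 15502 probe sets. Each had its real mean, a spread drawn from limma's variance prior and values independent of those of other probe sets. Of 100 probe sets changed by a log2 fold of 0.5, 82% were called, and of 100 changed by 1, 98% were called. Of the called probe sets 5.16% were unchanged ones, and camera called the 1 list that had been shifted and no other. Because the simulated values were independent, this does not show how camera behaves where the genes of a list vary together.

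The number of arrays limits the precision. The 27 bacterial control probe sets that were not spiked in had means of 5.83 to 7.04, with a median of 6.30. Of the tested probe sets, 5501 (35.5%) lay at or under 7.04 and carry little signal over background. Among the named genes tmsb, ctsll, uhrf1, cdk1 and anxa1a in controls, and arhgap29a, ldb3a and nt5c2l1 after the lesion, lay at or under that level. Their changes may therefore be understated. The genes ptf1a, hbba2, krt94, thbs4b and pdk2b lay there in both groups, so their changes rest on little signal. Arrays of the same group correlated at 0.991 to 0.998 across probe sets, and no array was a copy of another: the SD of the difference was at least 0.119 within a group and at least 0.456 between groups.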

Results

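Gene expression was measured in whole retinas of albino zebrafish, 4 control samples and 4 samples taken after 72 h of constant bright light, which destroys photoreceptors and is followed by their regeneration from Müller glia. The series asked which genes change while photoreceptors regenerate, with its title naming the heparin-binding growth factors midkine-a (mdka) and midkine-b (mdkb). Only the light lesion samples came from constant bright light, so effects of the light itself cannot be told apart from those of the lesion. All values are RMA values on the log2 scale, with means ± SD over n = 4 arrays per group. The 3′ minus 5′ difference of the array's GAPDH control probe sets, a sign of RNA quality or of labelling, was 0.0450 ± 0.0219 in controls and 0.213 ± 0.0562 in light lesion samples (exact permutation test, two-sided p = 0.0286, the smallest 4 against 4 arrays can give).

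The 2 midkine genes differed in their response. The mdkb transcript rose from 11.10 ± 0.05 in controls to 12.18 ± 0.60 after the light lesion, a 2.11-fold rise (log2 fold change 1.08, SE 0.24, adjusted p = 0.00613), and all 4 light lesion arrays lay above all 4 controls. The light lesion arrays spread widely for mdkb, from 11.45 to 12.69. The mdka transcript stood at 11.98 ± 0.09 in controls and 11.75 ± 0.17 after the lesion (log2 fold change -0.23, SE 0.08, adjusted p = 0.0554). All 4 light lesion arrays lay below all 4 controls, though narrowly (highest light lesion value 11.896, lowest control 11.908). The mdka difference was just short of the threshold. It passed under several other settings, always as a lower value, with adjusted p = 0.0254 at the least. The difference between the 2 genes' changes was 1.31 on the log2 scale (exact permutation test, two-sided p = 0.0286). Each gene was read by 1 probe set.

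Across the array 6232 of 15502 probe sets (40.2%) passed the threshold, 3029 higher and 3203 lower after the light lesion, and 689 changed at least 2-fold, 420 higher and 269 lower. Counted as genes, 3915 of 8793 changed, 477 of them at least 2-fold. Among the probe sets at or under the highest background mean, 920 were called. The largest rise was that of mmp9, a secreted matrix metalloproteinase, from 7.05 ± 0.08 to 10.80 ± 0.34 (13.4-fold, log2 fold change 3.74, SE 0.15, adjusted p = 1.94e-07). It was followed by the thioredoxin txnb (3.37 on the log2 scale), the neural transcription factor sox11b (3.31), the stress-responsive factor atf5a (3.31), the tetraspanin tspan36 (3.25), the mitochondrial uncoupling protein ucp2 (3.1), the ubiquitin-like isg15 (2.96), tmsb (2.96), rrm2l (2.95), the stress factor atf3 (2.92), ptgdsb.1 (2.79) and ctsll (2.61). The largest fall was that of gucy2f, a photoreceptor guanylate cyclase, from 12.05 ± 0.12 to 8.79 ± 0.23 (log2 fold change -3.26, SE 0.11, adjusted p = 1.23e-07). Also among the 12 largest falls were pde6a (-3.24), the transcriptional inhibitor id2b (-3.00), guca1b (-2.76), the ETS factor etv5b (-2.56), the mitochondrial carrier slc25a25a (-2.51), arhgap29a (-2.43), the retinal homeobox gene rx1 (-2.41), the carbonic anhydrase ca7 (-2.35), the phosphatase ptena (-2.27), gnb1b (-2.22) and the phosducin pdca (-2.19). Other probe sets of some of these genes changed in the same direction by less: gucy2f had a second at -1.68, sox11b others at 3.08 and 1.83, and pdca others at -1.77 and -1.04. In controls tmsb (6.98) and ctsll (6.03) lay under the highest background mean of 7.04 and mmp9 close to it. After the lesion arhgap29a (6.50) lay under it. The changes of these 4 genes may therefore be understated, and their ranks are uncertain.

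**Figure D1:**
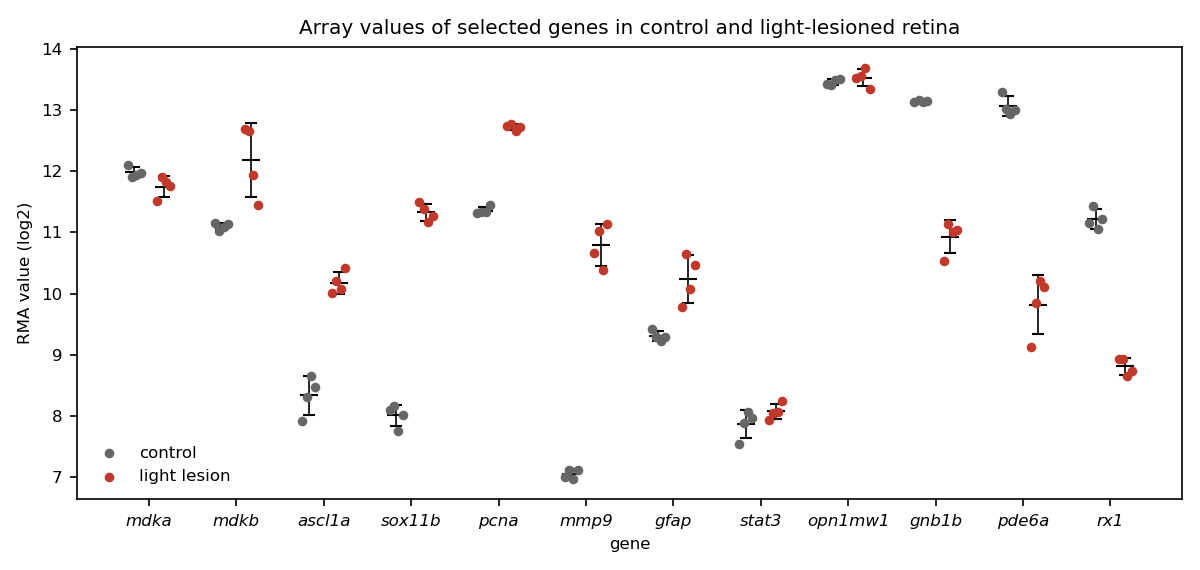
RMA values (log2, y axis) of 12 genes in each of the 4 control arrays (grey) and 4 light lesion arrays (red), with bars for the mean and SD of each group. The mdkb values after the lesion lie between 11.45 and 12.69, above all controls, while stat3 and opn1mw1 overlap between the groups.

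Genes of rod phototransduction and the rod outer segment fell together. Of 12 measured members 11 fell and 1 rose (counts adjusted over the list alone were 11 and 1), with a median log2 fold change of -1.61. The rod phosphodiesterase subunit pde6a (-3.24), the guanylate cyclase activator guca1b (-2.76) and the transducin subunit gnb1b (-2.22) fell most. The member that rose was nr2e3 (0.60, adjusted p = 2.77e-05), a nuclear receptor that specifies rods. Camera placed the rod list below the other genes (adjusted p = 1.71e-07 with the preset correlation, adjusted p = 0.106 with an estimated correlation).

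Cone genes fell less evenly. Of 22 measured members of the cone list 13 fell, 2 rose and 7 did not pass (13 and 4 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.00124, adjusted p = 0.292 with an estimated correlation). Besides gucy2f, the green opsin opn1mw4 (-1.71) and the guanylate cyclase gucy2d (-1.18) fell, while guca1aa (0.93) and the cone transducin subunit gngt2a (0.34) rose. The list counts gucy2f as a cone gene, but whole-retina RNA cannot show whether its fall was in cones or rods. Another green opsin, opn1mw1, stood at 13.45 ± 0.05 in controls and 13.52 ± 0.14 after the lesion (adjusted p = 0.477). After a second quantile normalization its difference was -0.19 and passed the threshold (adjusted p = 0.0375). The mean of the rod list fell more than that of the cone list, with a rod minus cone shift of -1.06 on the log2 scale (exact permutation test, two-sided p = 0.0286). The higher GAPDH 3′ minus 5′ difference of the light lesion arrays (0.168 on the log2 scale) separates the same groups. Its part in these falls was not tested.

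**Figure D2:**
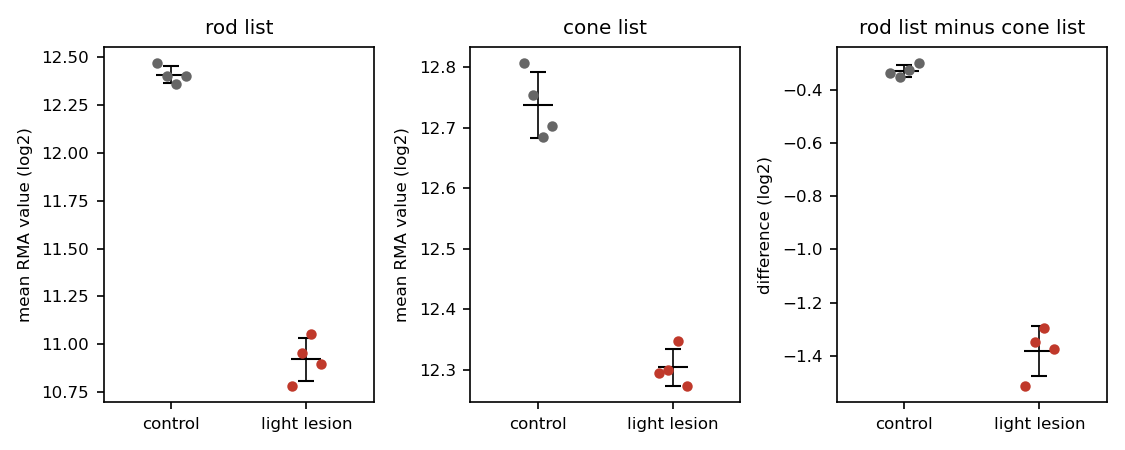
Mean RMA value (log2) over the 12 rod genes and the 22 cone genes, and their difference, for each of the 4 control arrays (grey) and 4 light lesion arrays (red), with bars for the group mean and SD. The rod minus cone difference lies between -0.35 and -0.30 in controls and between -1.51 and -1.30 after the lesion.

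Genes of the list of photoreceptor transcription factors moved apart. Of 11 measured, foxn4 (2.19), otx5 (0.84) and nr2e3 (0.60) rose and rx1 (-2.41), rx2 (-1.83) and samd11 (-1.72) fell, and 5 did not pass (5 higher and 3 lower adjusted over the list alone). The Müller glia reprogramming list also holds foxn4, and whole-retina RNA does not show in which cells foxn4 rose. Without genes held by several lists the median of this list turned negative. The list's median was 0.16, but its mean was -0.15 and camera's direction was down (adjusted p = 0.934). Of the other probe sets of foxn4, 1 rose by only 0.32 and 1 did not pass, at -0.08. Of 18 visual cycle and retinoid genes 6 rose and 2 fell, also adjusted over the list alone, with the retinoic acid binding proteins crabp2a (1.81) and crabp1a (1.58) and the retinol binding protein rbp2a (0.84) higher and rbp4 (-0.92) and rbp3 (-0.61) lower (list adjusted p = 0.315).

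Genes tied to the reprogramming of Müller glia, the radial glia from which zebrafish regenerate neurons, rose. Of 42 measured 25 rose, 6 fell and 11 did not pass (25 and 7 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.87e-04, adjusted p = 0.273 with an estimated correlation). The proneural factor ascl1a rose from 8.34 ± 0.32 to 10.17 ± 0.18 (3.57-fold, log2 fold change 1.83, SE 0.15, adjusted p = 1.24e-05), and mmp9, sox11b and the galectin lgals2a (2.59) rose further. The stem cell factor sox2 rose by 0.53 at its brightest probe set, while its other probe sets, at 0.24 and 0.03, did not pass. The signal transducer stat3 was 0.21 higher, which did not pass (adjusted p = 0.166), though it did with a background covariate added later (adjusted p = 0.0349). The eye field factor pax6b (-1.1) fell.

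Of 20 Müller glia genes 7 rose, 3 fell and 10 did not pass, also adjusted over the list alone. The fatty acid binding protein fabp7a (2.23), the transcriptional inhibitor id1 (1.26) and the intermediate filaments vim (0.94) and gfap (0.93, SE 0.16, adjusted p = 0.00148) rose, and the carbonic anhydrase cahz (-0.64), fgf24 (-0.25) and the glutamine synthetase glula (-0.21) fell. The list as a whole did not pass when tested against other genes (camera adjusted p = 0.366).

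Cell cycle genes rose. Of 49 DNA replication genes 45 rose, 1 fell and 3 did not pass (46 and 1 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 8.97e-14, adjusted p = 0.232 with an estimated correlation). The replication clamp pcna rose from 11.36 ± 0.06 to 12.72 ± 0.05 (2.57-fold, adjusted p = 1.48e-07), thymidylate synthase tyms by 1.81, the maintenance methylation factor uhrf1 by 1.81 (a second, dim probe set by 0.21) and the histone mRNA binding protein slbp by 1.70. The member that fell was rfc1 (-0.52), the large subunit of the clamp loader. Of 54 genes of mitosis and chromosome segregation 42 rose, none fell and 12 did not pass (43 higher and 1 lower adjusted over the list alone), with a median of 0.50 (camera adjusted p = 5.22e-11, adjusted p = 0.273 with an estimated correlation). The spindle checkpoint gene mad2l1 (2.21), cdca7a (2.08) and the mitotic kinase cdk1 (1.85) rose most.

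Markers of microglia and leukocytes rose. Of 28 measured 25 rose, none fell and 3 did not pass, also adjusted over the list alone, with a median of 0.84 (camera adjusted p = 4.88e-10, adjusted p = 0.106 with an estimated correlation). The galectin lgals9l1 rose by 2.53 and the granulins grna.1 and grna by 2.37 and 2.2. Of 30 genes of cytokine, STAT and inflammatory signalling 12 rose and 3 fell, also adjusted over the list alone (list adjusted p = 0.0617, under 0.05 with median centring or a trended prior). The signalling inhibitor socs3a rose by 2.38 beside mmp9 and isg15, while cisha (-0.53), ccl19a.1 (-0.33) and cxcl14 (-0.28) fell. Of 26 complement and acute phase genes 6 rose and 1 fell, also adjusted over the list alone, with c1qc at 1.51 and cfi at -0.94. Their median was -0.04, while the mean (0.16) and camera's direction were up (adjusted p = 0.883). Among these 26 genes 61.5% lay at background.

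Of the stress lists only that of oxidative stress passed with the preset correlation. Counts in these and the other lists stand against 3915 of 8793 genes called over the whole array, 2145 higher and 1770 lower. Of 32 oxidative stress genes 17 rose and 5 fell (18 and 5 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00124, adjusted p = 0.346 with an estimated correlation). Next to txnb and ucp2, the thioredoxin-binding txnipa rose by 2.18, while gpx1b (-1.16), gpx1a (-0.88), tp53inp1 (-0.61), sod2 (-0.29) and fth1a (-0.20) fell. Of 36 immediate early genes 15 rose and 4 fell (15 and 5 adjusted over the list alone), among them the AP-1 components jun (2.34) and fosab (1.83, other probe sets 0.64 to 1.23), against nr4a1 (-1.08), ccn2a (-0.60), btg1 (-0.49) and klf11a (-0.43). That list did not pass (adjusted p = 0.0617), but did without light lesion replicate 3 or 4. Of 43 heat shock and folding genes 17 rose and 11 fell (18 and 12 adjusted over the list alone), with hspb8 (1.16), the endoplasmic reticulum chaperone hspa5 (0.97) and xbp1 (0.91) higher and dnajb1b (-1.15) lower (list adjusted p = 0.369). Of 32 p53 and apoptosis genes 16 rose and 6 fell, also adjusted over the list alone, including bida (0.93), ccng1 (0.78) and baxa (0.74), with mdm4 at -0.43 (list adjusted p = 0.0888).

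Markers of amacrine, horizontal and bipolar cells, neurons of the inner retina, fell. In whole-retina RNA a changed share of a cell type cannot be told apart from a change within its cells. This holds for the other lists too. Of 31 amacrine and horizontal cell markers 21 fell and 1 was called higher (22 and 1 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 4.31e-07, adjusted p = 0.106 with an estimated correlation). The connexin gja9a (-1.1) and the homeobox genes prox1a (-1.03) and barhl2 (-0.89) fell, and ptf1a, at background in both groups with overlapping arrays, was 0.21 higher, a call lost in several omissions of 1 array. Of 11 bipolar cell markers 7 fell and none rose, also adjusted over the list alone, among them samsn1a (-0.79), isl1a (-0.61) and fezf2 (-0.58), with a list adjusted p = 0.0121 and adjusted p = 0.430 with an estimated correlation. Of 21 ganglion cell markers 12 fell and 4 rose, also adjusted over the list alone (list adjusted p = 0.0888, and 0.0473 without genes held by several lists). The neurofilament-related inab (-1.24), sncgb (-0.81) and the acetylcholine receptor subunit chrnb3a (-0.79) fell, while the tubulin tubb5 (2.51, a second probe set 1.40), the growth cone protein gap43 (1.21), the chemokine receptor cxcr4b (1.21) and thy1 (0.33) rose. Of 31 circadian genes 16 fell and 7 rose (16 and 9 adjusted over the list alone), with rorab (-1.67), the melatonin synthesis enzyme aanat1 (-1.25) and nr1d2b (-1.23) lower and bhlhe41 (2.21) higher (list adjusted p = 0.0860).

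Markers of cells outside the neural retina were included because a dissected retina can carry them. Of 11 pigment epithelium and pigment cell markers 6 rose and none fell, also adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.00671, adjusted p = 0.106 with an estimated correlation). They included tspan36 (3.25), the melanosome protein pmelb (2.18) and the melanin synthesis enzyme dct (1.03). Of 35 extracellular matrix genes 11 rose and 1 was called lower, also adjusted over the list alone (camera adjusted p = 0.0135, adjusted p = 0.504 with an estimated correlation). Its members that rose most, mmp9, anxa2a (2.27) and anxa1a (1.87), are a protease and calcium-dependent membrane binding proteins rather than matrix components. The member called lower, thbs4b (-0.13), lay at background in both groups and lost its call in several omissions of 1 array. Without genes held by several lists the call of this list was lost (adjusted p = 0.101). Among its measured genes 45.7% lay at background.

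The remaining lists of this kind did not pass as designed. Their shares of measured genes at background ran from 38.5% (lens) to 57.1% (corneal and skin epithelium). Not passing therefore says little about whether such cells were carried along. Of 28 corneal and skin epithelium markers 9 rose and 1 fell, also adjusted over the list alone, with anxa2a, anxa1a and icn (2.03) higher and krt94 (-0.29, at background in both groups) lower (adjusted p = 0.104, and 0.00231 without dim probe sets). Of 17 blood markers 3 fell, also adjusted over the list alone, namely hbba2 (-0.33, at background in both groups), nt5c2l1 (-0.30) and alas2 (-0.29), with a list adjusted p = 0.0617, under 0.05 with median centring or a trended prior. Of 28 muscle markers 6 fell and 1 rose (5 and 1 adjusted over the list alone), with ldb3a (-0.85), pvalb2 (-0.30) and mylz3 (-0.28) lower and eno3 (0.31) higher (adjusted p = 0.104). The call of pvalb2, whose groups overlap, was lost in several omissions of 1 array. Of 13 vascular markers efnb2a (-1.11) and aqp1a.1 (-0.41) fell, also adjusted over the list alone (list adjusted p = 0.267). Of 13 lens genes crygm4 was called lower (-0.22), a call lost when adjusted over the list alone and in most omissions of 1 array (list adjusted p = 0.532).

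Ribosomal protein genes rose together. Of 70 measured 69 rose and 1 fell, also adjusted over the list alone, with a median of 0.78 (camera adjusted p = 1.53e-31, adjusted p = 0.106 with an estimated correlation). The ribosomal proteins rps12 and rpl27a rose by 1.26 and 1.24 and the paralog rps27l by 2.36. The member that fell, rps6kal (-1.28), is a kinase that the name pattern of the list took in. The GAPDH 3′ minus 5′ difference (0.168) separates the same groups here too, and its part in these rises was not tested. Of 29 glycolysis genes 17 fell and 3 rose (17 and 4 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 8.26e-05, adjusted p = 0.106 with an estimated correlation). The regulator pfkfb1 (-1.15), triosephosphate isomerase tpi1a (-1.13) and the enolase eno1b (-0.97) fell, while pdk2b (0.59, at background in both groups), slc16a3b (0.56) and gapdh (0.34) rose. Of 87 oxidative phosphorylation genes 22 rose and 16 fell (25 and 16 adjusted over the list alone), with cox6b1 (1.01), sdhaf4 (0.71) and ndufa1 (0.55) higher and ndufs1 (-0.88) lower (list adjusted p = 0.521). Of 12 cholesterol synthesis genes msmo1 (-0.74) and fdft1 (-0.71) fell, also adjusted over the list alone (list adjusted p = 0.267).

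**Figure D3:**
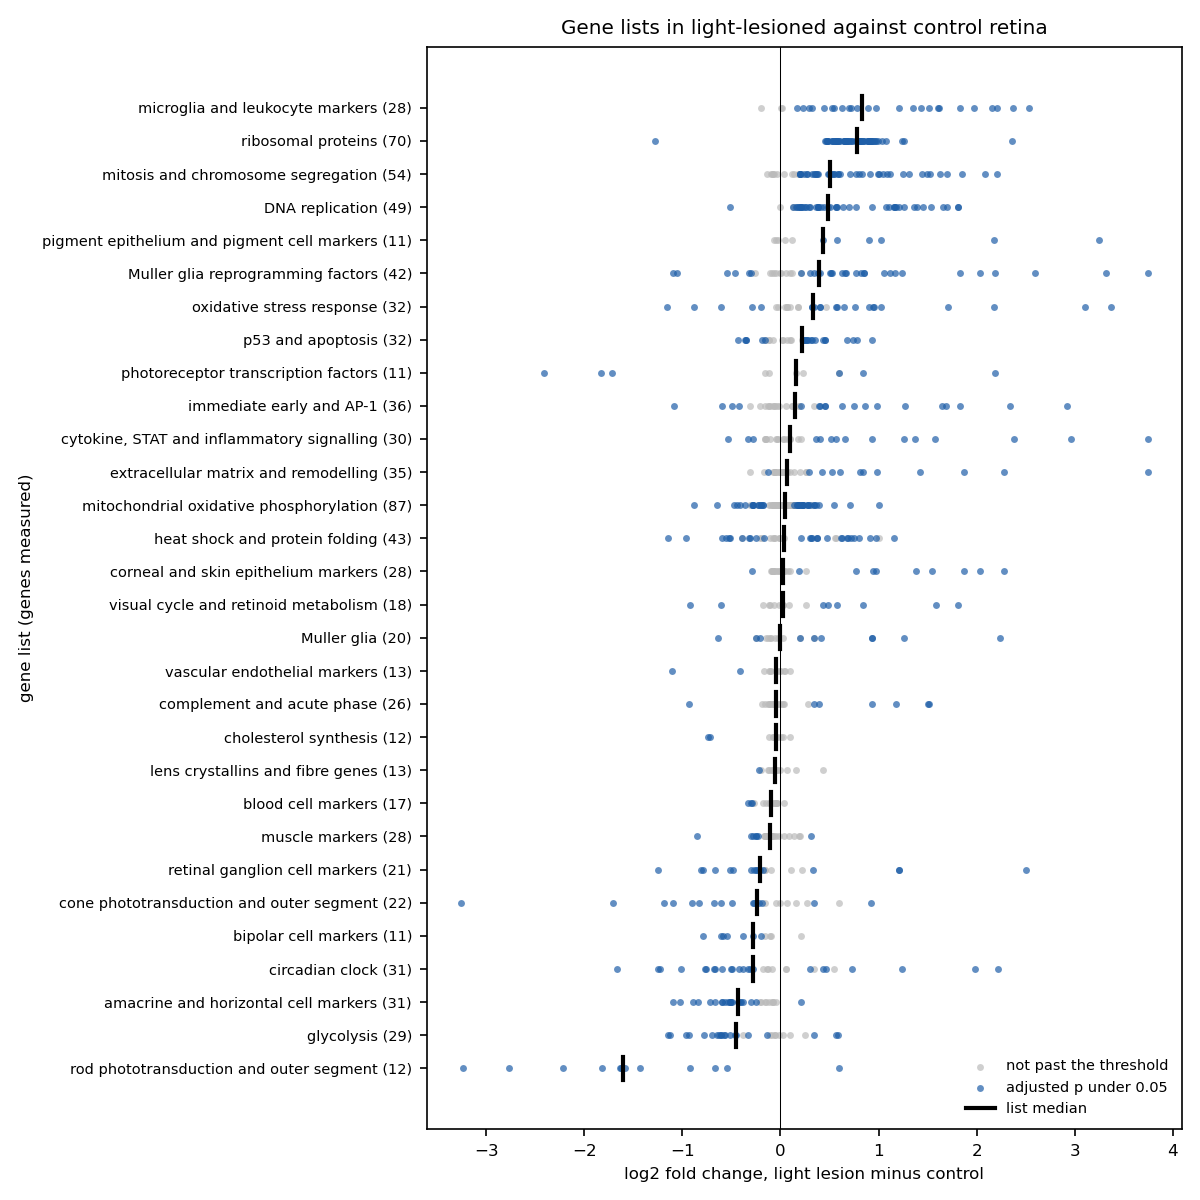
Log2 fold change (light lesion minus control, x axis) of each measured gene in the 30 gene lists (y axis, with the number of genes measured), blue where the adjusted p was under 0.05 and grey otherwise, with a black bar at the list median. Medians run from -1.61 for the rod list to 0.84 for microglia and leukocyte markers.

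With the preset correlation 13 of the 30 lists passed, 8 higher and 5 lower, and with a correlation estimated per list 0 did, the lowest adjusted p being 0.106, while fry called 25.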

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

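The tests on pigment markers, and the test of the probe sets as bright as mdka, were chosen after the result was seen. The interval on the share near mdka was likewise set against its bounds only once that share was known, as was the comparison of the scalings' effect with the SE of mdka. The single-gene changes had been seen before the other tests were set.

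Chance assignment of these 8 samples to the groups is unlikely to give the number of changed probe sets, but is not excluded. The real split was 1 of 35, the smallest share possible, which says nothing of the spread between fish. Of the 35 splits of the 8 arrays into 4 and 4, 1 split, the real one, gave as many as 6232, and likewise 1 gave as many as 689 changed at least 2-fold, with 0 as the highest of the other splits in both cases. Each other split mixes the groups and so carries their difference in its spread, which keeps its count low. The count of 0 in the other splits therefore adds no support.

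The rod list fell more than the cone list. Bright probe sets near the ceiling of the array could hide a fall of cone genes. Without members above a control mean of 13, 8 of 12 rod and 11 of 22 cone genes were left. Their rod minus cone shift was still -0.89, with no overlap between the groups' arrays. Only 1 of the 22 cone members lay under 9, where background could hide falls, too few to account for the difference, and without it the shift was -1.01. Whether the higher GAPDH 3′ minus 5′ difference of the light lesion arrays (0.168) bears on the shift was not tested. A difference between rods and cones in their response to light stays open, untested.

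Midkine-b rose and midkine-a did not. Saturation of the mdka probe set could hide a rise and stays open: of 503 probe sets within 0.5 of its control level 15 were called at least 2-fold higher, or 2.98% (exact 95% interval 1.68 to 4.87), against bounds of under 1% if saturated and at least 2% if not, so that the interval lies above the first bound but includes the second. Of all probe sets 2.71% were called at least 2-fold higher, but rises of other probe sets do not show that the mdka probe set itself could rise. Whether a shift of the bright range hides a rise is undecided: mdka stayed lower after a second quantile normalization and after median centring (the higher value -0.22), but these moved probe sets as bright as mdka by a median of only 0.0150 and 0.00668, less than the SE of mdka (0.0845), so this test says nothing. The probe sets as bright as mdka had a median of -0.16 and quartiles of -0.52 and 0.17, which does not settle it either, and a biological difference between the 2 genes stays open, untested.

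Pigment cell markers rose. More pigment epithelium RNA in the lesioned samples could raise all of them alike, and this stays open. The genes tspan36 and pmelb rose by 1.69 more than dct on the log2 scale (exact permutation p = 0.0286), but they are the 2 largest rises of the list, so the difference excludes nothing. The rise of dct exceeded that of rpe65a by 0.45 (exact permutation p = 0.0571), and rpe65a and rgrb lie above 13 in controls, where the array may compress changes. A change of these genes within cells of the retina or in another cell type was not tested.

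In 10 of 306 groups of 4 arrays, against 15.3 that chance gives at 5%, 1 array stood far from the other 3, with a gap beyond Dixon's 95% critical value. In controls these were nr2e3 in replicate 1 (0.907 of the range), foxn4 in replicate 3 (0.922), cdk1 in replicate 3 (0.903), gja9a in replicate 1 (0.878), rps12 in replicate 2 (0.866) and pdk2b in replicate 3 (0.841). In light lesion arrays they were nr4a1 in replicate 1 (0.945), gpx1b in replicate 3 (0.860), ldb3a in replicate 2 (0.914) and cox6b1 in replicate 2 (0.930). The GAPDH control probe sets, which no comparison of genes uses, had a 3′ minus 5′ difference 0.168 higher in light lesion arrays than in controls (exact permutation p = 0.0286).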

How the results depend on the processing

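The background covariate and the other probe sets of named genes were chosen after the data were seen. Of 1914 values of the 119 named genes other than mdka and mdkb under the alternatives, 1878 kept direction and side of the threshold, 33 lost the call, 1 (stat3 with the background covariate, 0.31, adjusted p = 0.0349) gained it and 2 reversed. The lost calls were those of sox2 at its other probe sets and of ptf1a, crygm4, pvalb2 and thbs4b, each under the replicate block and under several omissions of 1 array, thbs4b also after a second quantile normalization and crygm4 and pvalb2 also with the background covariate. Of 567 values of the 30 lists 514 kept both, 14 lost the call, 25 gained it and 14 reversed. The labels give no pairing, and the values showed no sign of one by replicate number, though so few samples cannot exclude it. Correlations of same-numbered deviations were -0.21, 0.28, -0.24 and 0.17, and 2 of 8 samples correlated best with their own number. With the replicate block 5638 probe sets were called, and the rod minus cone shift of -1.06 had an exact sign-flip p = 0.125, the smallest that 4 pairs allow. Averaging the probe sets of a gene gave 4014 changed (1866 lower) and 454 changed at least 2-fold (153 lower), fewer because fewer units are tested. The mdka difference passed the threshold at -0.22 after a second quantile normalization (adjusted p = 0.0420), at -0.23 without dim probe sets (0.0454), with the trended and robust prior (0.0437) and with averaged probe sets (0.0471), and at -0.28 with the background covariate (0.0254); its adjusted p ran from 0.0254 to 0.124. Without 1 array it ran from -0.28 (without light lesion replicate 2, adjusted p = 0.0325) to -0.15 (without light lesion replicate 1). The cause was not tested. The lists called numbered 0 with an estimated correlation and 25 with fry, against 13. After a second quantile normalization opn1mw1 was at -0.19 (adjusted p = 0.0375), the Müller glia median at -0.0154 and that of oxidative phosphorylation at -0.0231. The other foxn4 probe set was at -0.0755. The photoreceptor transcription factor median was -0.0749 with averaged probe sets and -0.92 without genes held by several lists, where the Müller glia median was -0.057. With the background covariate the Müller glia median was -0.00904, complement 0.00328 and lens 0.0231. Without dim probe sets complement was at 0.64 and muscle at 0.19. Without 1 array the Müller glia median ran from -0.0129 (without control replicate 3) to 0.042 (without light lesion replicate 4), and lens from -0.0997 to 0.00416 (without control replicate 3). Lists called numbered 15 with the replicate block, with median centring and with the trended prior, and 14 without dim probe sets. Cytokine signalling gained a call under the first 3 of these (adjusted p = 0.0421, 0.0494 and 0.0472), immediate early genes under the block (0.0498), blood markers under median centring (0.0494) and the prior (0.0472), corneal and skin markers without dim probe sets (0.00231) and ganglion cell markers without genes held by several lists (0.0473). Lists gained calls without 1 array as follows: cytokine signalling without light lesion replicate 3, immediate early genes without light lesion replicate 3 or 4, blood and muscle markers without control replicate 1. The cause of these changes was not tested. A pseudocount of 16 was not run, because the values were already logarithms, and array weights and the variance prior do not apply to the rod minus cone shift. Signal over background limits what the dim probe sets show.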

Other observations

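Proteasome genes rose with the ribosomal proteins. Grouping genes by the start of their symbol, a grouping made after the data were seen, gave 132 families of at least 8 genes. All 12 measured psmb genes and all 8 psma genes, which encode the core particle of the proteasome, rose, with medians of 0.72 and 0.82, as did 13 of 14 psmd genes (median 0.48) and 6 of 8 psmc genes (median 0.40) of its regulatory particle. Families tied to ubiquitin did not pass: of 29 ube genes 9 rose and 7 fell (adjusted p = 0.638), of 24 usp genes 4 and 7 (adjusted p = 0.398), of 35 rnf genes 2 and 9 (adjusted p = 0.344), of 17 fbxo genes 2 and 2 (adjusted p = 0.920) and of 15 trim genes 0 and 5 (adjusted p = 0.166). Of 51 eif genes, mostly translation initiation factors, 29 rose and 4 fell (median 0.29). Of 58 atp genes, which include ion pumps and ATP synthase subunits, 6 rose and 26 fell (median -0.17). Camera at the preset correlation called 13 of the 132 families, and with an estimated correlation the adjusted p of those named here was 0.592 for psmb and psma, 0.616 for psmd, psmc and eif and 0.656 for atp.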
